A study of Mus musculus with 12 samples.

How the data were processed

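RNA sequencing had measured transcripts in 12 libraries of cardiomyocytes isolated from newborn mouse hearts, 3 libraries in each of 4 groups. Per the labels, pups had injections each day from postnatal day 0 to 1 of N-acetylcysteine (NAC), a thiol antioxidant and cysteine donor, at a dose called high and in saline with 25 mM HEPES and 140 mM NaCl, or with saline as the control. On day 2 the pups had either an occlusion of the left anterior descending coronary artery (myocardial infarction, MI) or a sham procedure, and hearts were collected on day 3. Cells came from digested ventricles of pooled hearts and were selected with an isolation kit for neonatal cardiomyocytes. The series text speaks of whole ventricles and the sample labels of the left ventricle. RNA was extracted with Trizol, and libraries were made after poly-A enrichment.

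The deposited table held normalized values (signal) for 52336 genes: gene read counts that the authors had divided by a single size factor per library. Multiplied by the factor of its library, 100% of the values came within 0.01 of a whole number, so whole reads could be recovered. The size factors equalled the median-of-ratios factors recomputed from these reads in all 12 libraries. The submitters' processing notes name STAR 2.7.10a, DESeq2 1.44.0 and the mouse genome build mm10. The gene counter, the annotation release and the strand setting were not given in the sources used here. Gene symbols, positions and types came from the reference annotation by gene identifier, which matched 52027 of the 52336 identifiers. The 21590 genes at 0 in every library, and other genes with a mean normalized value under 10 over the 12 libraries, were left out, which left 14996 genes.

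The recovered depth was 14353842 to 25118341 reads per library, and 19031 to 23753 genes had reads. For genes with 0 reads in a group, a lower bound of the fold change was computed against a floor of 3 reads over the group. For genes with 1 to 3 reads in a group, the ratio was given with its exact 95% counting interval. Such floors and intervals were computed on reads summed over a group and leave out the spread between libraries. Reads without molecular identifiers are not independent molecules, so the intervals can be too narrow for counting error as well.

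The values were transformed as log2(value + 1) and tested with limma 3.58.1 in R 4.3.3, with a trended prior variance, in 1 model of 4 group means over all 12 libraries (8 residual degrees of freedom). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 14996 genes. A gene counted as changed at an adjusted p under 0.05. The comparisons were MI against sham after saline, MI against sham after NAC, NAC against saline after sham surgery, NAC against saline after MI, the interaction of NAC and MI, and NAC against saline averaged over both surgeries. The replicates are not stated to come from separate animals or litters, and the cells were pooled, so the p-values measure the spread between these libraries. An exact permutation test of 3 libraries against 3 cannot give a p under 0.1.

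Before the data were examined, 39 lists of genes were fixed from textbook knowledge (26 of pathways and 13 of cell type markers), along with the comparisons, the test, the rule for named genes and all alternatives except those listed as added. Of 892 symbols in the lists, 880 were matched to an identifier. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Lists with fewer than 5 measured members were not tested: those of skeletal muscle (4 measured) and of lung and liver (3 measured), which left 37. A list score is the mean log2 value of its members in a library. Some genes are in more than 1 list, so the lists are not independent. Among the measured markers, 2 of 15 for neutrophils (Il1r2 and Lcn2) and 4 of 16 for fibroblasts (Tcf21, Col1a1, Col1a2 and Col3a1) are in another list.

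The rule for named genes took, per comparison, the 10 highest and 10 lowest fold changes among genes that passed, had a mean of at least 50 in the higher group, had all libraries of a group above all of the other, and had a symbol that was not a predicted or clone name. For the interaction and the averaged comparison the rule took 5 each way and did not ask for separated libraries. Where no gene passed, it took the 5 smallest p-values each way among genes that met the conditions on name and level, and these are named as not passing. It added up to 4 members of each list with the smallest p, and always took Nppa, Nppb, Myh6, Myh7, Mki67, Ccnb1, Cdk1, Cdkn1a, Hmox1, Nqo1, Gclc, Slc7a11, Txnrd1, Sod2 and Gdf15. Values are given for a part of these genes. In the results of the comparisons, genes named outside the rule are marked as such. Where single libraries are described and in the closing sections, genes such as Xist are named without a mark. Some genes that the rule took are not reported here.

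Each count, correlation, named gene and list call was recomputed with a pseudocount of 0.5 and of 5, without a filter on low values, with a minimum mean of 50, after rescaling by TMM factors and by upper quartiles, with the quasi-likelihood test of edgeR 4.0.16 and with DESeq2 1.42.0 on the recovered reads, with the libraries of a comparison only, with library quality weights, with the title prefix as a block in the NAC comparisons, and without each library in turn. After the data were seen, 2 alternatives were added: leaving out NAC sham replicate 2 and NAC MI replicate 2 together, and the sum of 4 Y-linked genes as a covariate. Where a library was left out, the spread was still pooled over all groups. An exact permutation of NAC and saline labels within each surgery was also added for the list scores and the globin share, with 400 arrangements and a smallest possible p of 0.005.

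The test was checked on simulated counts. They were drawn for each gene around its mean over all 12 libraries, with changes added in saline MI or in NAC MI. In each of 5 runs 100 genes with a mean of at least 50 were changed at each fold. Genes were drawn independently, without shifts shared within a library. A 2-fold change was recovered in 22.6% of genes for MI against sham after saline and in 27.6% for NAC against saline after MI. An 8-fold change was recovered in 97.6% and 97.0%. All recovered genes had the right direction, and 5.6 and 6.0 unchanged genes were called per run.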

Results

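The data comprised 12 RNA sequencing libraries of cardiomyocytes isolated at postnatal day 3 from mice injected with NAC or saline on days 0 to 1 and given MI or sham surgery on day 2. There were 3 libraries in each of the 4 groups: saline sham, NAC sham, saline MI and NAC MI. The recovered depth was 14644891, 16925515 and 17190858 reads in NAC sham, 19774078, 15323911 and 17636815 in saline sham, 17796632, 14353842 and 15993567 in NAC MI, and 18116190, 25118341 and 19677556 in saline MI. Values below are normalized read counts, given as mean ± SD with n = 3 libraries per group unless stated, and genome positions are on GRCm38 (mm10). Sample titles carried prefixes of unstated meaning. R207 stood on saline sham 1 and 2 and NAC sham 2, R219 on saline sham 3, R230 on NAC MI 3 and saline MI 1 and 2, and R235 on NAC MI 1 and 2 and saline MI 3, while NAC sham 1 and 3 had none. No prefix held both sham and MI libraries, so surgery and prefix cannot be told apart.

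Markers of other cell types and of RNA content differed between libraries. The macrophage and monocyte score was 8.79 in NAC sham 2 against 5.02 to 6.09 in the other 5 sham libraries, and 5.29 in NAC MI 2 against 8.44 to 9.12 in the other 5 MI libraries. All 20 macrophage markers were lower in NAC MI 2 than the mean of NAC MI 1 and 3, with log2 differences from -2.03 (Ptprc) to -4.54 (Ms4a7), and 16 of 20 were at least 2-fold higher in NAC sham 2 than in NAC sham 1 and 3. Transcripts encoded in the mitochondrial genome took 16.3 ± 10.3% of reads in saline sham, 19.4 ± 4.90% in NAC sham, 27.2 ± 2.82% in saline MI and 25.7 ± 3.49% in NAC MI. Globin transcripts, which mark red blood cells, took 4.66 ± 1.63%, 1.65 ± 0.893%, 5.33 ± 1.51% and 2.14 ± 0.685% in the same groups. Saline sham 3, the only R219 library, also stood apart within its group. It had 27.7% of mitochondrial reads against 7.65% and 13.6% in saline sham 1 and 2. Its ribosomal protein score was 13.3 against 12.3 and 12.2. Its library quality weight was 0.268, with 0.250 in NAC sham 2 and 0.451 in NAC MI 2.

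**Figure D1:**
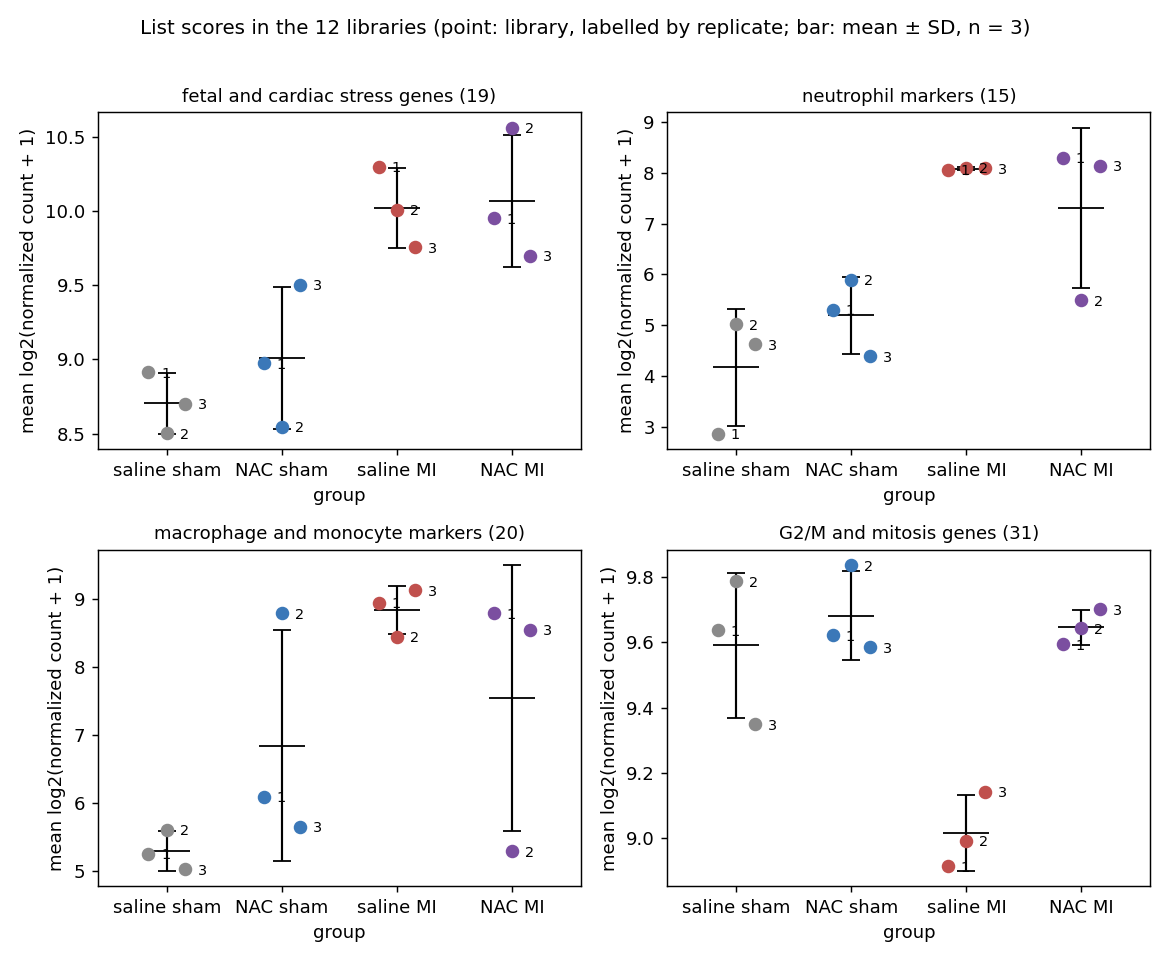
List scores (mean log2 of normalized count + 1 over a list's members) in each library, by group, for 4 lists, with points for libraries, numbered by replicate, and bars for mean ± SD (n = 3). The neutrophil score was 8.05 to 8.10 in saline MI and 2.86 to 5.01 in saline sham, the macrophage score of NAC MI 2 was 5.29, and the G2/M score was 8.91 to 9.14 in saline MI and 9.59 to 9.70 in NAC MI.

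The first comparison asked what MI changed in the isolated cells of saline-treated pups a day after surgery. The isolates held transcripts of other cell types too, with an endothelial score of 12.5 and a fibroblast score of 11.2 in saline sham. Which cells carried the changed transcripts was not tested. More white blood cells in the isolate after MI thus cannot be told apart from changes within cardiomyocytes. Lists of cardiac stress, inflammatory and matrix genes and of neutrophil and macrophage markers were higher after MI at the preset correlation, though most of their members did not pass over all genes. With an estimated correlation none of these 5 lists passed (adjusted p from 0.0999 to 0.183). Sprr1a, a small proline-rich protein induced in stressed tissue (ENSMUSG00000050359, chromosome 3, 92483952 to 92485895), went from 0.793 ± 1.37 in saline sham to 434 ± 134 in saline MI (log2 fold change 8.12, SE 0.544, adjusted p = 2.1e-05 in limma). It had 2 reads in saline sham and 1416 in saline MI, a ratio of 700 with a 95% counting interval of 194 to 5787. Spp1, which encodes the secreted matrix protein osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), rose from 7.59 ± 0.961 to 4417 ± 1638 (log2 8.93, SE 1.30, adjusted p = 0.00747). Arg1, the arginase of myeloid cells in repair, rose from 4.25 ± 3.42 to 1021 ± 158, and Csf3r, the receptor for granulocyte colony-stimulating factor, from 10.5 ± 10.6 to 885 ± 144. The list of genes of G2 phase and mitosis was lower at the preset correlation, with 0 of 31 members called over all genes and an adjusted p = 0.0999 with an estimated correlation.

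In that comparison limma called 129 of 14996 genes, 128 higher and 1 lower after MI. All 129 had separated groups, as had 2786 genes in all (18.6%, where chance gives 10%). The gene that fell was Gm47087, a predicted gene named outside the rule after its values were seen, from 28.0 ± 17.8 to 1.12 ± 1.11. Of the 19 measured fetal and cardiac stress genes, 19 were higher, 4 rose over all genes and 10 when adjusted over the list alone (median log2 1.06, adjusted p = 2.4e-13). Among them were Nppb, the B-type natriuretic peptide (597 ± 55.0 to 2743 ± 1296), Acta1, skeletal alpha-actin (2045 ± 641 to 5368 ± 797), and Cnn1, calponin (196 ± 105 to 1107 ± 320). Cnn1 is also in the list of mural cell markers. Nppa, the atrial natriuretic peptide, went from 60.0 ± 29.0 to 405 ± 126 and did not pass (adjusted p = 0.0722). With an estimated correlation the list had an adjusted p = 0.0999, and none of the 22 lists that passed in this comparison did so then (adjusted p from 0.0999). The always-named genes other than Nppb did not pass, from Mki67 at -0.81 to Nppa at 2.79.

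Some markers of white blood cells rose after MI with saline. Of 15 neutrophil markers, 15 were higher, 7 rose over all genes and 15 when adjusted over the list alone (median log2 3.50, adjusted p = 1.3e-20 and, with an estimated correlation, adjusted p = 0.0999). The 7 were Csf3r, Mmp9, Il1r2 and Stfa1, and, named outside the rule, S100a9, Cxcr2 and Camp. Mmp9, a gelatinase of neutrophils, went from 32.6 ± 18.4 to 959 ± 191. Of 20 macrophage and monocyte markers, 20 were higher, 2 rose over all genes (Cd14, the lipopolysaccharide co-receptor, and Ccr2, the monocyte chemokine receptor) and 20 when adjusted over the list alone (median log2 3.34, adjusted p = 1.3e-20, estimated correlation adjusted p = 0.141). Of 33 inflammatory genes, 28 were higher, 4 rose over all genes and 20 when adjusted over the list alone (median log2 2.26, which is unchanged with its 1 member at 0 set to the floor, and adjusted p = 0.183 with an estimated correlation). Il1b, the cytokine interleukin-1 beta, had a log2 fold change of 6.95, and Cxcl2, a chemokine for neutrophils, went from 15.4 ± 10.1 to 638 ± 344. Marco, a scavenger receptor of macrophages, had 0 reads in saline sham and 222 in saline MI, at least 73.2-fold higher. Hcar2, a receptor for nicotinate, had 2 and 283 reads, a ratio of 140 (38.4 to 1161), and Il1r2, the decoy receptor for interleukin-1, 3 and 331, a ratio of 109 (37.0 to 532).

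Matrix genes were also higher with MI after saline: 30 of 32 were higher, 3 over all genes (among them Timp1, an inhibitor of metalloproteinases, and Spp1) and 23 when adjusted over the list alone (median log2 0.85, adjusted p = 1.1e-16, estimated correlation adjusted p = 0.137). Fibroblast markers were higher in 16 of 16, 0 over all genes and 6 when adjusted over the list alone (median log2 0.63, estimated correlation adjusted p = 0.287), with Col1a1, a chain of collagen I, at 22422 ± 4706 and 50396 ± 10923. Krt8 and Krt18, the paired keratins of simple epithelia, rose in the epicardial list (12 of 14 higher, 5 when adjusted over the list alone, median log2 0.75, estimated correlation adjusted p = 0.319). Krt8 (ENSMUSG00000049382, chromosome 15, 101996698 to 102004482) went from 50.9 ± 12.7 to 470 ± 119. All 31 genes of G2 phase and mitosis were lower, 0 over all genes and 16 when adjusted over the list alone (median log2 -0.58, adjusted p = 2.6e-16, estimated correlation adjusted p = 0.0999). Ccnb1, cyclin B1, stood at 916 ± 251 and 568 ± 46.8, and Cdk1, its kinase, at 1370 ± 234 and 916 ± 117. Of 21 genes of cholesterol synthesis, 17 were lower, 0 over all genes (median log2 -0.48, estimated correlation adjusted p = 0.138), and all 16 endothelial markers were lower, 0 when adjusted over the list alone (median log2 -0.59, estimated correlation adjusted p = 0.482). NRF2 targets, genes induced by oxidants, rose as a list (21 of 25 higher, 2 when adjusted over the list alone, median log2 0.29, and 0.50 without saline sham 3, estimated correlation adjusted p = 0.319), with Slc7a11, the cystine transporter, at 11.7 ± 8.64 and 43.9 ± 10.3.

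Of 31 named genes that passed with saline, Sprr1a, Csf3r, Il1r2 and Krt18 also passed without any single library, and Spp1, Arg1, Fgr, Hcar2, Cnn1, Ccr2 and Mmp9 failed only without saline MI 1 (adjusted p from 0.0521 to 0.0685). The other 20 failed without at least 3 of the 6 libraries in turn, with the highest adjusted p of a gene between 0.0824 and 0.249. The 129 genes became 39, 83 and 105 without saline sham 1, 2 and 3 and 15, 43 and 29 without saline MI 1, 2 and 3, and edgeR and DESeq2 called 91 and 464.

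The next comparison asked the same of pups that had received NAC, with the same limit on which cells carried the transcripts. Keratins, 1 of 19 stress genes and 2 of 33 inflammatory genes rose after MI here too, and the lists of stress and inflammatory genes passed at the preset correlation but not with an estimated correlation (adjusted p = 0.152 and 0.311). Cell cycle genes of G2 phase and mitosis stood at a median log2 of -0.0009 (15 of 31 higher, adjusted p = 0.969). Sprr1a had 0 reads in NAC sham and 1386 in NAC MI, at least 526-fold higher (0 and 524 ± 179, adjusted p = 6.2e-06 in limma). Krt8 rose from 34.5 ± 30.6 to 919 ± 718, Krt18 from 69.6 ± 20.4 to 697 ± 413, and Acta1 from 1156 ± 299 to 4992 ± 1440. Serpina3n, a serine protease inhibitor of the acute phase, rose from 36.6 ± 22.8 to 654 ± 220. Cxcl5, a neutrophil chemokine, had 1 read in NAC sham and 238 in NAC MI, a ratio of 271 (48.1 to 10740), and Hcar2 3 and 229, a ratio of 86.9 (29.4 to 424).

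With NAC, limma called 19 genes, all higher after MI. All 19 had separated groups, as had 2855 genes in all (19.04%, where chance gives 10%). Besides the named genes they held Chil1, S100a6, Emb, Trf, Mirt1 and Rab11fip1, named here outside the rule, as is the noncoding 4833412C05Rik. Of 19 fetal and cardiac stress genes, 17 were higher, 1 rose over all genes (Acta1) and 12 when adjusted over the list alone (median log2 0.95, adjusted p = 2.2e-11, estimated correlation adjusted p = 0.152). Fhl1, a LIM protein of stretched muscle, went from 3165 ± 344 to 6816 ± 1305 and missed the threshold (adjusted p = 0.0546), as did Spp1, from 58.6 ± 91.9 to 3575 ± 2944 (0.0620). Of 33 inflammatory genes, 30 were higher, 2 rose over all genes and 11 when adjusted over the list alone (median log2 1.52, and 2.50 and 0.60 without NAC sham 2 and 3, estimated correlation adjusted p = 0.311). Of 15 neutrophil markers, 15 were higher, 1 over all genes (Il1r2) and 8 when adjusted over the list alone (median log2 2.25, estimated correlation adjusted p = 0.304). Il1r2 is also in the list of inflammatory genes. Macrophage markers rose as a list by a median log2 of 0.58 (17 of 20 higher, 0 over all genes, 1 when adjusted over the list alone, adjusted p = 0.0330, estimated correlation adjusted p = 0.721). Their median was 0.38, 1.43 and 0.07 without NAC sham 1, 2 and 3 and -0.09, 1.61 and 0.16 without NAC MI 1, 2 and 3, and the call held without NAC sham 2 or NAC MI 2 alone.

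Epicardial markers were higher after MI with NAC in 14 of 14, and 2 rose over all genes (Krt8, Krt18) and 7 when adjusted over the list alone (median log2 1.28, 1.98 without NAC sham 3 and 0.54 without NAC MI 2, estimated correlation adjusted p = 0.283). Of 22 glycolysis genes, 21 were higher, 0 over all genes and 6 when adjusted over the list alone (median log2 0.46, estimated correlation adjusted p = 0.304). They included Pgam1, phosphoglycerate mutase (900 ± 92.8 to 1527 ± 79.1), and Slc16a3, a lactate exporter (182 ± 53.8 to 741 ± 339). Hypoxia genes followed (18 of 23 higher, 5 when adjusted over the list alone, median log2 0.30, 0.18 without NAC sham 1 and 0.13 without NAC MI 1, estimated correlation adjusted p = 0.111), with Bnip3, a mitophagy receptor, at 282 ± 83.4 and 615 ± 126. NRF2 targets rose as a list (24 of 25 higher, 0 over all genes, 3 when adjusted over the list alone, median log2 0.33, and 0.60 without NAC sham 2, estimated correlation adjusted p = 0.304), with Akr1b8, an aldose reductase, at 111 ± 34.9 and 413 ± 191. Matrix genes were higher in 30 of 32, 1 over all genes (Timp1) and 9 when adjusted over the list alone (median log2 0.62, estimated correlation adjusted p = 0.304), and all 43 ribosomal protein genes were higher, 0 when adjusted over the list alone (median log2 0.50, estimated correlation adjusted p = 0.426). Mural cell markers were lower in 9 of 11, 0 over all genes and 6 when adjusted over the list alone (median log2 -0.70, estimated correlation adjusted p = 0.152). Of all 19 lists that passed after NAC, 0 passed with an estimated correlation. The always-named genes ran from Mki67 at -0.41 to Nppa at 2.41, with 0 passing (smallest adjusted p = 0.179).

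Of 13 named genes that passed with NAC, Sprr1a, Krt8, Ptprn, Krt18 and Acta1 also passed without any single library. Cxcl5 failed without NAC sham 3 (adjusted p = 0.0519) and Serpina3n without NAC sham 1 (0.0776), and the other 6 without at least 3 of the 6 libraries in turn. The 19 genes became 8, 67 and 10 without NAC sham 1, 2 and 3 and 32, 33 and 22 without NAC MI 1, 2 and 3, and edgeR and DESeq2 called 28 and 241. With the libraries of this comparison only, limma called 1 gene, Sprr1a.

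The changes after MI went the same way under both treatments for most genes that passed. Of the 128 genes that rose after saline, 127 were also higher after MI with NAC, 84 of them at an unadjusted p under 0.05, with a median log2 of 3.30 after saline and 1.52 after NAC. These genes were chosen for passing after saline, which favours a higher median there, so the 2 medians do not show a difference between treatments. Of the 19 genes that rose after NAC, 17 were among the 128, against 0.162 if the lists were independent, and the other 2 were Olr1, a receptor for oxidized lipoproteins, and 4833412C05Rik. Both comparisons use the same spread estimate for a gene and the same split of surgery by title prefix, so independence is not a fair baseline. Across all genes tested, the MI changes under the 2 treatments, which share no libraries, had a Pearson r of 0.565 and a Spearman rho of 0.549. Genes are not independent replicates, and leaving out each library in turn gave r from 0.424 to 0.630 (jackknife SE 0.193), while without the filter on low values r was 0.334. The difference between the treatments is tested by the interaction.

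**Figure D2:**
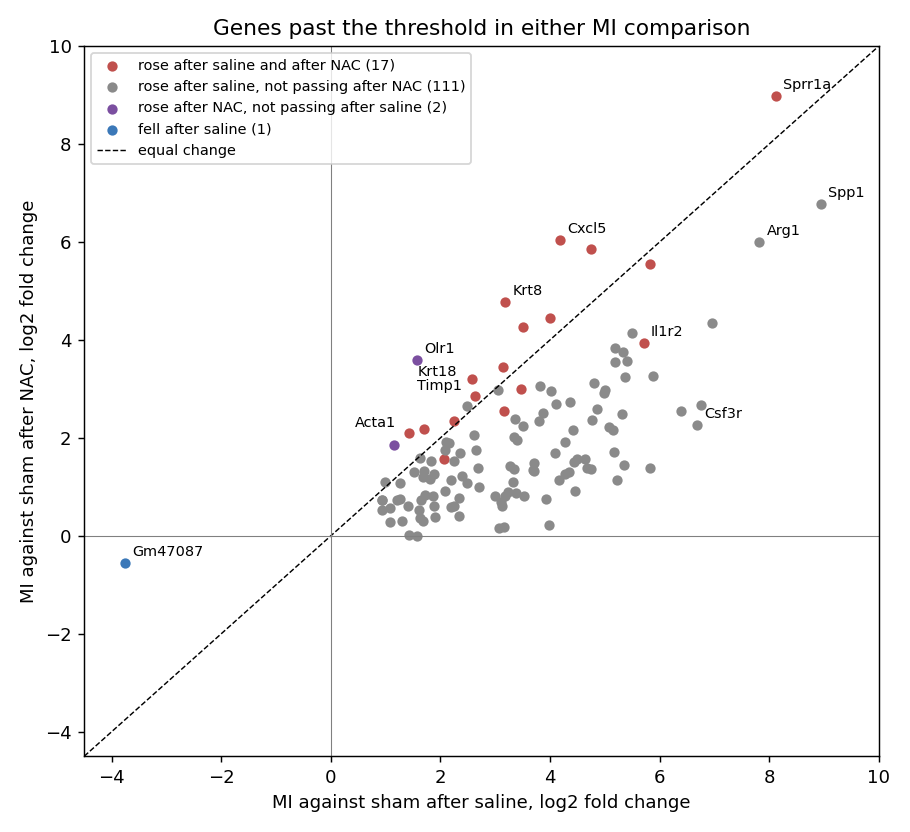
Log2 fold change of MI against sham after saline (horizontal axis) and after NAC (vertical axis) for genes that passed in either comparison, with points for genes and a dashed line where both changes are equal. 17 genes rose under both treatments, and the 128 genes that rose after saline, a choice that favours saline, had a median of 3.30 after saline and 1.52 after NAC.

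The third comparison asked what NAC changed in the cells of pups with sham surgery. In limma 0 of 14996 genes passed (smallest adjusted p = 0.580), so none of the genes named here is called, and they are given by their values. With library quality weights limma called 421 genes. The title prefix as a block leaves 1 NAC library, NAC sham 2, against saline sham 1 and 2, so its count is not given. Pnpla7, a lysophospholipase, stood at 176 ± 30.9 with NAC and 61.6 ± 3.49 with saline, and Nceh1, a cholesteryl ester hydrolase, at 944 ± 179 and 316 ± 124. Slc8a1, the sodium-calcium exchanger, stood at 9556 ± 3500 and 2798 ± 802, and Atp2a2, the calcium pump of the sarcoplasmic reticulum, at 53238 ± 28890 and 15868 ± 1811. Hbb-bt, a beta-globin (ENSMUSG00000073940, chromosome 7, 103812524 to 103813996), stood at 9419 ± 4696 and 36733 ± 22578. Rps2-ps10 (chromosome 18, 61259008 to 61259972) and Rpl34-ps1 (chromosome 6, 71124610 to 71124963), at 1654 ± 193 and 3641 ± 1259 and at 414 ± 58.1 and 1054 ± 598, are annotated as processed pseudogenes and can share reads with the parent genes, so the source of these reads was not settled.

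Unadjusted, 884 genes had a p under 0.05 for NAC after sham surgery against 749.8 by chance, and 9.86% of genes had separated groups against 10% by chance. edgeR called 0 genes and DESeq2 53 (46 higher). Ribosomal protein genes fell as a list with NAC: 41 of 43 were lower, 0 over all genes and 0 when adjusted over the list alone (median log2 -0.50, adjusted p = 1.3e-12, estimated correlation adjusted p = 0.737). Their median was -0.12 without saline sham 3 and -0.20 with the title prefix as a block, the same as within R207. Immediate early genes, which respond to stimuli and to handling of cells, fell as a list too (24 of 27 lower, 0 when adjusted over the list alone, median log2 -0.82, adjusted p = 8.2e-07, estimated correlation adjusted p = 0.737). Egr1 stood at 7026 ± 9469 and 13963 ± 938, and Junb at 3042 ± 3586 and 6913 ± 1471. The list's median was -0.36 without NAC sham 1, -1.47 without NAC sham 2 and 0.51 with the prefix block, which rests on NAC sham 2 and saline sham 1 and 2, so that the fall is not seen within R207.

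Of the 17 lists that passed for NAC after sham surgery, these 2 alone passed without any single library, and 0 of 17 passed with an estimated correlation (adjusted p from 0.468). Macrophage markers were higher in 20 of 20 (median log2 1.58, 0 over all genes and when adjusted over the list alone) but at 0.50 without NAC sham 2 (adjusted p = 0.0672), with the title prefix block at 3.24. Antioxidant enzymes were lower in 25 of 29 (median log2 -0.22, and -0.15 and -0.03 without NAC sham 2 and saline sham 3, which did not pass, and -0.35, -0.45 and -0.44 without NAC sham 1 and saline sham 1 and 2), and the call ended in the prefix block (-0.14, adjusted p = 0.127), with Gpx1, glutathione peroxidase 1, at 4066 ± 1443 and 8660 ± 4764. DNA damage repair genes were higher in 19 of 26 (median log2 0.30, and 0.10 without saline sham 3, adjusted p = 0.158, with 0.16 in the prefix block). Sarcomere and contraction genes were higher in 22 of 38, 2 when adjusted over the list alone (Slc8a1 and Kcnj2, an inward rectifier potassium channel). Their median log2 was 0.17, and it was -0.13, 0.67 and -0.04 without NAC sham 1, 2 and 3, 0.33 and 0.04 without saline sham 1 and 2, and -0.87 in the prefix block. Without NAC sham 2, limma called 80 genes (62 higher, 18 lower). The 15 always-named genes ran from Cdkn1a at -0.64 to Myh7 at 1.54 (smallest adjusted p = 0.770), with Nqo1, a classic NRF2 target, at 147 ± 51.9 and 198 ± 97.7.

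The fourth comparison asked what NAC changed in the cells of pups with MI. All 31 genes of G2 phase and mitosis were higher in NAC MI than in saline MI, and the list passed at the preset correlation but not with an estimated correlation (adjusted p = 0.0602). In limma the comparison called 0 of 14996 single genes (smallest adjusted p = 0.529), so none of the genes named here passed over all genes. Hmmr, a microtubule-binding protein of the mitotic spindle (ENSMUSG00000020330, chromosome 11, 40701395 to 40733422), stood at 690 ± 161 with NAC and 276 ± 52.9 with saline (log2 1.31, SE 0.215). Anln, the actin-binding protein anillin of the cleavage furrow, stood at 1410 ± 55.4 and 735 ± 58.8, Ckap2, a spindle protein, at 547 ± 45.7 and 304 ± 18.6, and Bub1, a kinase of the spindle checkpoint, at 518 ± 43.1 and 240 ± 75.6. Ccnb1 stood at 993 ± 109 and 568 ± 46.8 and Mki67, the proliferation antigen Ki-67, at 2688 ± 376 and 1448 ± 754. Among the genes with the smallest p on the lower side, Hbb-bt stood at 13582 ± 4132 and 48305 ± 10145, Col26a1, a collagen, at 277 ± 67.0 and 562 ± 44.1, and Fam214b at 474 ± 77.3 and 828 ± 12.8.

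The G2 and mitosis list had 0 members called over all genes and 19 of 31 when adjusted over the list alone (median log2 0.59, adjusted p = 1.2e-20, estimated correlation adjusted p = 0.0602). The list's median was 0.47 to 0.71 without each library in turn, 0.62 with the title prefix as a block, 0.88 within R230 and 0.50 within R235, and its score was 9.59 to 9.70 in NAC MI, 8.91 to 9.14 in saline MI and 9.35 to 9.84 in the sham libraries. DNA damage repair genes rose as a list (21 of 26 higher, 0 when adjusted over the list alone, median log2 0.28, 0.19 without NAC MI 3, estimated correlation adjusted p = 0.775, prefix block 0.30), with Brca1 at 284 ± 58.1 and 185 ± 38.6. Ribosomal protein genes fell as a list (41 of 43 lower, 0 when adjusted over the list alone, median log2 -0.33, -0.51 without saline MI 3, estimated correlation adjusted p = 0.775, prefix block -0.22). Lymphocyte markers fell as a list (6 of 7 lower, 2 when adjusted over the list alone, median log2 -1.92, -0.91 without NAC MI 2, estimated correlation adjusted p = 0.775), and the call ended in the prefix block (-1.51, adjusted p = 0.0529). Cd79b, a component of the B cell receptor, stood at 18.4 ± 16.8 and 73.0 ± 24.4.

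The other 8 of the 12 lists that passed for NAC after MI lost the call without at least 1 library, and 0 of 12 passed with an estimated correlation (adjusted p from 0.0602). Macrophage markers were lower in 20 of 20 (median log2 -1.31) but at -0.26 without NAC MI 2 (adjusted p = 0.618). Without the same library the median of endothelial markers went from -0.53 to -0.04, of epicardial markers from 0.82 to 0.28 and of sarcomere genes from 0.26 to 0.04, none of which then passed. Immediate early genes were lower in 26 of 27 (median log2 -0.58), with medians of -0.18 and -0.33 without NAC MI 2 and saline MI 1, where the list did not pass, and -0.19 in the prefix block. Ttn, the giant sarcomere protein titin, stood at 25186 ± 13570 and 6246 ± 1919. Unadjusted, 1382 genes had a p under 0.05 against 749.8 by chance, 20.3% of genes had separated groups against 10% by chance, edgeR called 0, DESeq2 11 and limma with library quality weights 685, and limma called 4 without NAC MI 3, the Y-linked Eif2s3y, Kdm5d, Ddx3y and Uty, named outside the rule. The 15 always-named genes ran from Hmox1, heme oxygenase 1, at -0.99 to Mki67 at 1.001. Across genes, the NAC changes after sham surgery and after MI had a Pearson r of 0.234 and a Spearman rho of 0.406 (r from 0.123 to 0.346 without each library in turn, jackknife SE 0.217), and genes are not independent replicates.

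The interaction asked whether the effect of NAC differed between MI and sham surgery. In 31 of 31 genes of G2 phase and mitosis the difference between NAC and saline was higher after MI than after sham surgery, and none of them passed (median log2 difference 0.55, adjusted p = 8.1e-21, estimated correlation adjusted p = 0.0588). Macrophage markers differed the other way in 20 of 20 (median -2.78, -1.73 without NAC MI 2, estimated correlation adjusted p = 0.482), as did 15 of 15 neutrophil markers (median -1.72, -0.95 without saline sham 1 and -0.66 without NAC MI 2, estimated correlation adjusted p = 0.482). Without NAC sham 2 and NAC MI 2 together, the macrophage difference was -0.74 and passed at the preset correlation (adjusted p = 5.0e-05), and the neutrophil difference was -0.38 and did not (adjusted p = 0.108). Among the genes the rule named, Mtfr2, a mitochondrial fission regulator, had a log2 difference of 1.74 (SE 0.465) and Ckap2 of 0.71 (SE 0.235), and on the lower side Pnpla7 had -1.58 (SE 0.352) and Csf3r -4.42 (SE 1.25). None of these genes passed.

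For the interaction, limma called 0 of 14996 genes (smallest adjusted p = 0.9999), with 305 at an unadjusted p under 0.05, fewer than the 749.8 by chance. edgeR called 0 and DESeq2 1 (Gm21188, lower, named outside the rule). Of 37 lists, 11 passed and 0 with an estimated correlation, and the 3 lists given above alone passed without any single library. The 15 always-named genes ran from Hmox1 at -1.36 to Ccnb1 at 0.91. Without NAC MI 3 limma called the same 4 Y-linked genes as for NAC after MI.

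Averaged over both surgeries, NAC was compared with saline in 6 libraries against 6. No single gene passed. Lists of mitosis and DNA repair genes were higher with NAC, and those of ribosomal protein and immediate early genes and erythroid markers lower, at the preset correlation only (0 of 14 lists passed with an estimated correlation). The immediate early list stood at 0.18 in the prefix block, and the erythroid call ended there and without saline sham 2. Hmmr had a log2 change of 1.02 (SE 0.152) and Hbb-bt of -1.88 (SE 0.299), both with an adjusted p of 0.126 in limma. Nceh1 (1.34, SE 0.212), Dsc2, a desmosomal cadherin of heart muscle (1.65, SE 0.275), and Slc8a1 (1.61, SE 0.281) stood on the higher side, and Rps2-ps10 (-1.02, SE 0.166) and Phlda3, a p53 target (-0.61, SE 0.116), on the lower side. All 43 ribosomal protein genes were lower, 4 when adjusted over the list alone (median log2 -0.43, -0.26 without saline sham 3, prefix block -0.24, estimated correlation adjusted p = 0.833). Of 31 genes of G2 phase and mitosis, 28 were higher, 7 when adjusted over the list alone (median log2 0.30, prefix block 0.38, estimated correlation adjusted p = 0.536), and of 26 DNA damage repair genes 20 were higher, 0 when adjusted over the list alone (median log2 0.34, 0.22 without saline sham 3, prefix block 0.20, estimated correlation adjusted p = 0.661). The G2 and mitosis score differed between NAC and saline by 0.0904 after sham surgery and by 0.63 after MI. Erythroid markers were lower in 11 of 13, 4 lower and 1 higher when adjusted over the list alone (median log2 -0.67). The median was -0.57 without saline sham 2 (adjusted p = 0.0787), -0.44 without saline sham 3 and -0.16 in the prefix block, where the list did not pass.

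In the averaged comparison limma called 0 of 14996 genes, with 2327 at an unadjusted p under 0.05 against 749.8 by chance. edgeR called 0, DESeq2 437, limma with the prefix block 6 and limma with library quality weights 2021. The block takes its part after sham surgery from NAC sham 2 as the only NAC library. Without NAC sham 2, saline sham 2 and NAC MI 3, limma called 250, 4 and 9 genes. Of 14 lists that passed, 6 passed without any single library and 0 with an estimated correlation. Antioxidant enzymes were lower in 24 of 29 (median log2 -0.20) and did not pass without NAC sham 2 (-0.11) or saline sham 3 (-0.06) or in the prefix block (-0.13, adjusted p = 0.0684). NRF2 targets were lower in 19 of 25 (median log2 -0.17, and -0.25 without saline sham 1) but at 0.03 in the prefix block. They did not pass without NAC sham 1 or 3 (-0.13 and -0.15), saline sham 2 or 3 (-0.13 and -0.06), NAC MI 1 or 2 (-0.17 and -0.14) or saline MI 2 (-0.18). Immediate early genes were lower in 25 of 27 (median log2 -0.69, -1.12 without NAC sham 2) but at 0.18 in the prefix block. The 15 always-named genes ran from Cdkn1a at -0.45 to Nppa at 1.19.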

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

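All tests of explanations in this part were chosen after the results they address were seen. In 11 of 37 lists the effect of NAC differed between MI and sham surgery by a test of the interaction at a preset correlation. The differences in median log2 change were 0.5461 for G2/M and mitosis, 0.1296 for G1/S and DNA replication, 0.3538 for cholesterol synthesis, 0.4099 for glucocorticoid-responsive genes and 0.5765 for epicardial markers. On the other side they were -2.785 for macrophage and monocyte markers, -1.717 for neutrophil markers, -0.5241 for NADPH oxidase and oxidant producers, -0.5245 for the interferon response, -0.2637 for extracellular matrix and wound healing and -0.24 for mural cell markers. With an estimated correlation none of the 11 passed, and only G2/M and mitosis, macrophage and neutrophil lists passed without each library in turn. Without NAC sham 2 and NAC MI 2 together, the macrophage difference was -0.7409 and G2/M and mitosis stood at 0.6353, both past the threshold at the preset correlation, while the neutrophil difference was -0.3833 and did not pass.

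The other 8 differences lost the call without at least 1 library. For NADPH oxidase and oxidant producers this was so without NAC sham 2 (-0.42) and NAC MI 2 (-0.38), with -0.0246 without both. For the interferon response it was so without NAC sham 2 (0.11), saline sham 1 (-0.41), NAC MI 1 (-0.62) and NAC MI 2 (-0.38), with 0.327 without NAC sham 2 and NAC MI 2. The matrix list lost it without NAC sham 2 and 3 (-0.12 each), saline sham 1 and 3 (-0.21 and -0.10), NAC MI 3 (-0.05) and saline MI 1 and 3 (-0.25 and -0.13), with -0.12 without NAC sham 2 and NAC MI 2. Cholesterol synthesis lost it without NAC sham 3 (0.23) and NAC MI 2 (0.17) and stood at 0.20 without saline sham 2. Epicardial markers lost it without NAC sham 1 (0.46) and NAC MI 2 (0.007) and stood at 0.92 without NAC sham 3 or NAC MI 1, with -0.18 without NAC sham 2 and NAC MI 2. Glucocorticoid-responsive genes lost it without NAC sham 1 and 3 (0.35 and 0.21), saline sham 2 (0.15), NAC MI 1 (0.26) and saline MI 1 and 3 (0.31 and 0.37) and stood at 0.68 without NAC sham 2. Mural cell markers lost it without NAC sham 2 (-0.29), saline sham 1 and 2 (-0.30 and -0.19), NAC MI 2 and 3 (-0.36 and -0.35) and saline MI 1 (-0.28), and were between -0.39 and -0.44 without NAC sham 1 or 3, saline sham 3, NAC MI 1 or saline MI 2. The list of G1/S and DNA replication lost it without NAC sham 1 (0.12), saline sham 1 and 2 (0.09 and 0.07), NAC MI 1 and 3 (0.14 and 0.08) and saline MI 3 (0.16).

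Macrophage markers were high in NAC sham 2 and low in NAC MI 2, and no marker of this list is in another list. Exchanged labels between the 2 libraries were argued against, since the fetal and cardiac stress score of NAC MI 2 lay 1.06 above the highest other sham library and that of NAC sham 2 lay 1.15 below the lowest other MI library. A difference between title prefixes was argued against, since the macrophage score of NAC sham 2 lay 3.18 above the highest other library of its prefix and that of NAC MI 2 lay 3.50 below the lowest of its own. A changed share of cardiomyocytes as the whole cause was argued against, since against the other 2 libraries of the group the fibroblast score moved by -0.0545 in NAC sham 2 and -0.0403 in NAC MI 2, and the macrophage score by 2.91 and -3.38. A change in part stays open, since endothelial markers moved by 0.91 and -1.27, and the sarcomere score was 11.8 in NAC sham 2 against 13.5 and 13.4, and 13.5 in NAC MI 2 against 13.0 and 12.8. The interferon score also stood apart, at 8.67 in NAC sham 2 against 5.91 to 6.30 in the other sham libraries. In NAC MI 2 it was 5.83 against 6.38 to 6.87 in the other MI libraries. More or fewer white blood cells carried through the isolation kit, or a differing response of the pooled pups, may explain the pattern, and both stay open.

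Genes of G2 phase and mitosis were higher after MI with NAC than with saline. As the whole cause, the sex of the pooled pups was argued against by a median of 0.6971 with Y-linked genes as a covariate. The lower leukocyte content of NAC MI 2 was argued against by 0.6589 without that library, and a difference between title prefixes by 0.6172 with the prefix as a block, each past the threshold at the preset correlation. An effect of NAC on cells dividing after MI may remain as a hypothesis, but which cell type carries these transcripts was not tested, and with an estimated correlation the list had an adjusted p = 0.0602.

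Immediate early genes were lower after sham surgery with NAC than with saline. A lower share of cells other than cardiomyocytes cannot be told apart from NAC: without NAC sham 2, which does not show the fall, endothelial markers had a median of -0.65, fibroblast markers of 0.026 and macrophage markers of 0.5027, whose call depended on the setting (adjusted p = 0.0672, and 0.000383 without NAC MI 2 as well). Nor can a difference between title prefixes: with the prefix as a block the median was 0.5062, but the only NAC library in R207 is NAC sham 2, which stands apart in its macrophage markers. Handling during cell isolation may also move these genes and was not tested.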

How the results depend on the processing

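The alternatives that left out NAC sham 2 and NAC MI 2 together and that used Y-linked genes as a covariate were chosen after the data were seen, as were the tests on other splits. Of 152 gene values, 149 were never reversed and 39 kept the same call in every setting; of 95 list calls, 77 were never reversed and 36 kept their call in every setting except the estimated correlation, where none of them passed. The counts of genes for MI after saline stayed within 1.5 times of 129 with both pseudocounts, both rescalings, edgeR and a minimum mean of 50.

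For MI after NAC limma called 43 genes with a pseudocount of 5 and 10 with a minimum mean of 50, where fewer genes were tested. DESeq2 called 53 genes for NAC after sham surgery, 11 for NAC after MI, 464 for MI after saline, 241 for MI after NAC, 1 for the interaction and 437 for the averaged comparison. With the libraries of a comparison only, limma called 507 for MI after saline and 1 for MI after NAC. Library quality weights gave 421 for NAC after sham surgery, 685 for NAC after MI, 2915 for MI after saline, 806 for MI after NAC and 2021 for the average. The title prefix block gave 154 for NAC after sham surgery and 6 for the average. Without NAC sham 2 and NAC MI 2 limma called 278 for NAC after sham surgery, 607 for MI after saline, 381 for MI after NAC and 167 for the average. The Y-linked covariate gave 70 for MI after saline and 12 for MI after NAC. Without a filter, the correlation of the MI changes was 0.3344. Using the libraries of a comparison only changed no fold change, nor did leaving out NAC sham 2 and NAC MI 2 for MI after saline. Those counts thus differ through the estimate of the spread alone. For the other settings, except where fewer genes were tested, the cause was not tested.

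With the prefix block the NAC change after sham surgery was reversed for Junb (0.2266), Egr1 (0.3413) and Myh7 (-0.3759). After sham surgery R207 alone holds both treatments, so the block values are those of NAC sham 2 against saline sham 1 and 2. The part of the averaged comparison after sham surgery rests on the same NAC library. The block also reversed the lists of NRF2 targets (0.1128), sarcomere (-0.8748), cardiomyocyte proliferation regulators (-0.0915), immediate early genes (0.5062), endothelial (0.2819), erythroid (0.5054) and atrial markers (-0.016). In the averaged comparison it reversed NRF2 targets (0.03221), sarcomere (-0.3372) and immediate early genes (0.1793). Without NAC sham 2 and NAC MI 2 the reversed lists were the interferon response for NAC after sham surgery (-0.1872), MI after NAC (0.5259) and the interaction (0.3272), oxidative phosphorylation for MI after NAC (-0.1822) and epicardial markers for the interaction (-0.1845). Library quality weights reversed oxidative phosphorylation (-0.08363) and the interferon response (0.07317) for MI after NAC. Both lists were also reversed there without NAC sham 2 alone (-0.0987 and 0.1247), and interferon for NAC after sham surgery stood at the same -0.1872. The tests given above did not settle why NAC sham 2 differed, and the cause of the other reversals was not tested.

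Leaving out each library in turn gave 0 to 80 genes for NAC after sham surgery, 0 to 4 for NAC after MI, 15 to 105 for MI after saline, 8 to 67 for MI after NAC, 0 to 4 for the interaction and 0 to 250 for the average. Without each library in turn, list medians that were reversed ranged from -0.1154 to 1.058 (mitochondrially encoded), -0.1327 to 0.671 (sarcomere) and -0.1872 to 1.088 (interferon) for NAC after sham surgery, and from -0.0703 to 0.5157 (oxidative phosphorylation) for MI after saline. For MI after NAC they ranged from -0.0987 to 0.4941 (oxidative phosphorylation), -0.8928 to 0.1247 (interferon) and -0.08587 to 1.611 (macrophage), and for the interaction from -0.765 to 0.1142 (interferon). A group left with 2 libraries was assumed to vary like the other groups. No paired analysis was possible because the labels give no replicate numbers that pair libraries across groups, and the title prefix, whose meaning is not stated, was used as a block.

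Other splits of the same 6 libraries are too few for a share under 0.05 in the comparisons of 3 against 3. For NAC after sham surgery the real split called 0 genes and the highest other 10, and for NAC after MI 0 and 1. With a real count of 0 each of the 10 splits had to call at least as many. For MI after saline the real split called 129 and the highest other 677. As many were called by 2 of 10 splits, the real one among them, and the median of the others was 0. For MI after NAC the values were 19 and 511, again with 2 of 10 and a median of 0. In each comparison the other split that reached the real count called several times as many, which points to a structure of the samples. With NAC it set NAC sham 1 and 3 and NAC MI 2, at macrophage scores of 5.3 to 6.1, against libraries at 8.5 to 8.8. With saline it set saline sham 1 and 2 and saline MI 3, at ribosomal protein scores of 12.2 to 12.7, against libraries at 13.0 to 13.3. These scores were picked after the splits were seen, and the cause was not tested. For the interaction and the average, the real count was 0, so that all 100 of 100 drawn splits had to call as many, and the highest others were 2 and 15. These splits say nothing about chance. In simulated genes drawn independently, without shifts shared within a library, a 2-fold change was recovered in 22.6% for MI after saline.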

Other observations

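The tests in this part were chosen after the results were seen. Without NAC sham 2, the NAC libraries after sham surgery were set apart from saline by 80 genes in limma (62 higher, 18 lower), of which 10 belonged to the list of sarcomere and contraction genes, all higher, and 6 to the immediate early genes, all lower. Myh7, a slow myosin heavy chain, had a log2 change of 2.36, Atp2a2, the calcium pump, 2.14, Ryr2, the calcium release channel, 1.85 and Erbb4, the neuregulin receptor, 2.91. Junb, Egr1 and Fosb, transcription factors of the early response, had -2.82, -3.21 and -4.52. The 2 remaining NAC libraries carry no title prefix while all 3 saline sham libraries carry one, so NAC and prefix are not separable in this comparison. Their sarcomere scores were 13.5 and 13.4 against 12.2 to 12.7 in saline sham, and their endothelial scores 11.9 and 11.6 against 12.4 to 12.5. Their macrophage scores went the other way, at 6.09 and 5.65 against 5.02 to 5.61. A differing share of cardiomyocytes cannot be told apart from changes within these cells.

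Exact permutation of NAC and saline within each surgery gave 6 of 37 list scores at a p under 0.05 and 0 after adjustment over the lists. Here and for the globin share below, labels were exchanged across title prefixes, which NAC and saline libraries did not hold evenly. The DNA damage repair score was higher with NAC by 0.277 on average, with all 6 NAC libraries above all saline libraries of their surgery (exact p = 0.005, the smallest possible, adjusted 0.185). Ribosomal protein genes had a difference of -0.403 (exact p = 0.025, adjusted 0.259) and G2/M and mitosis 0.36 (exact p = 0.035, adjusted 0.259). For G2/M and mitosis the difference was 0.0904 after sham surgery and 0.63 after MI. Immediate early genes had a difference of -0.755 (exact p = 0.13, adjusted 0.481).

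Globin transcripts took a 2.74-fold lower share of reads with NAC than with saline (log2 difference -1.452, exact p = 0.005, the smallest possible). Less blood in the NAC libraries is a candidate explanation. The 9 erythroid markers other than adult globins had a median log2 change of -0.3596 with an SD of 0.832, against -1.57 for the 4 globins, and 7 of 9 were lower, among them Alas2 (-1.11), an enzyme of heme synthesis, while Tfrc, the transferrin receptor, stood at 1.47. Their spread leaves it open, and less blood cannot be told apart from other causes here.

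The sex of the pools differed between the MI libraries. NAC MI 1 and 2 had a sum of 0 for 4 Y-linked genes and Xist, the transcript of the inactive X chromosome, at 8841 and 8953. NAC MI 3 and saline MI 3 had Xist at 0 and Y-linked sums of 2170 and 2596. Saline MI 1 had Xist at 19.1 and saline MI 2 at 1607, with Y-linked sums of 1681 and 764, and all 6 sham libraries held both kinds of transcript.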
